A study of Mus musculus with 6 samples.

How the data were processed

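RNA of 6 primary mouse lung tumour lines, 3 labelled non-SMC and 3 labelled SMC, was hybridised to Agilent whole-genome arrays with 1 dye, Cy3. Per the labels' protocols, the lines came from tumours of mice with conditional Rb1 and Trp53 alleles, total RNA was isolated with TRIzol, and it was amplified and labelled with a low-input single-colour kit. Per the file headers, the scans were quantified with Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes), and the array design is numbered 014868. The deposited intensity per spot that was used is the processed signal, which per the file headers is background-subtracted within the array and is not normalized between arrays. The median spot intensity and the local background intensity, as deposited, are not normalized. The deposited series table holds log2 values whose quantiles are equal in all columns (medians 5.07), that is, quantile-normalized; each column correlated at 0.996 or more with log2 of the processed signal of its own array and at no more than 0.961 with any other array. Its scale and direction were settled by this comparison, and it is not centred per gene. Steps before this that no header or label records are not given in the sources used here.

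Control spots (1639) and spots with outlier flags were left out, spots of the same probe were averaged, and log2 of the processed signal minus the array's 75th percentile over non-control probes was used. That percentile ranged from 485 to 696 intensity units. A probe was kept if well above background on all arrays of at least 1 group. Probes left without any usable spot on an array numbered 50. Of 41174 probes, 27479 were given a gene symbol by matching the transcript accession, without versions, to a RefSeq table of assembly GRCm38.p6. The remaining 13695 were kept unnamed, and no coordinates were used, since the file headers name the older build mm9. Where several probes of a gene were kept (5155 genes), the brightest over all arrays stood for it. Among the named genes, another probe had the opposite sign for Tpm1. This gave 19848 features, 13322 named. Of 688 list genes, 673 were on the array and 588 were tested.

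The planned fit was limma (lmFit and eBayes) with pair and group, two-sided, with Benjamini-Hochberg adjustment over all features. It had 2 residual and 2.07 prior degrees of freedom. The pairs come from the labels, which give each line its pair and call the lines paired. Deviations from the group means correlated at -0.01, 0.14 and 0.00 between the lines of pairs 1 to 3. Lines of different pairs gave -0.15 to 0.13, the highest for non-SMC replicate 1 with SMC replicate 3, the arrays that lay off the slide shared by the others. These correlations over all features therefore do not show the pairing. Lists were tested with camera (preset correlation 0.01), with camera using an estimated correlation, and with fry, adjusted over 27 lists. In this fit, the p-value of a gene measures the spread between 3 pairs of lines, and this number limits the precision. Camera sets the genes of a list against all other genes. With the preset correlation, its p-value treats genes as the units and does not measure the spread between the 3 pairs. A probe not well above background on every array of a group has only a bound there: "at least N-fold" sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among probes well above background. These bounds hold only for the brightest probe and the planned processing. Over the other settings, the difference was as small as -5.10 for Axl and 0.565 for Robo2. For genes detected on only some arrays of a group, the fitted difference includes signals not well above background, and the number of arrays is given. Among the 28 such named genes past the threshold, setting these signals to the same floor made the difference smaller by 0 to 1.51 (log2), a calculation added after the data were examined.

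The design, the gene lists and the alternatives were fixed before the data were examined. So was the rule for named genes: the 12 largest increases and 12 largest decreases with a symbol among features past the threshold with 1 sign in all 3 pairs (filled, if fewer, with the smallest unadjusted p and said not to pass; this was not needed); per list up to 4 members past the threshold with the largest difference, or, if none passed, the 2 with the largest difference as values; Rb1, Trp53, Neurod1, Yap1, Pou2f3, Cdh1, Vim, Myc, Mycl, Mycn, Nfib, Notch1, Hes1 and Rest in every case; and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty as a check of the sex labels. Some genes that this rule names are not reported here. Tyrobp and the genes named only in the closing section were chosen after their values were seen.

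Alternatives were quantile normalization, median scaling, normexp (offset 50) with the 75th percentile, the deposited log2 values, no filter, detection on all arrays, the mean of a gene's probes, no replicate block, the slide as a block or its shared slide alone, an intensity trend, robust variance, a 2-fold minimum, and leaving out each pair. The slide block set the slide that held both groups against the other slides, pooled into a single level. Normexp was planned on the mean spot intensity and was run on the median spot intensity with the local background median, the columns used here. Leaving out single non-SMC arrays, and the estimated correlation without the block, were added after the data were examined.

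The code was tested on simulated data built from the pair means and residual spread of the 19848 features, with 200 changed. Of the features changed by 2, 4 and 8 on the log2 scale, 0%, 85.1% and 95.5% were called, each with the right sign in 100%, with 5 false calls. Differences of 4-fold were therefore out of reach in this simulation. The rate depends on the share of features changed, so it does not carry over directly to the data. R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9 were used.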

Results

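Gene expression was measured in 6 primary cell lines grown from lung tumours of mice that carried conditional alleles of Rb1 and Trp53, a model of small cell lung carcinoma. The labels sort the lines into 3 pairs, and each pair holds 1 line called non-SMC and 1 line called SMC; the abbreviation is not spelled out in the labels. Each group therefore had 3 lines, with 1 array per line. Pairs 1 and 3 are labelled female and pair 2 male. Between 26386 and 28197 of the 41174 probes were well above background on an array (64.1% to 68.5%), no probe was saturated, and 19848 features were tested, of which 13322 carried a gene symbol. All values below are log2 signals relative to the 75th percentile of their array, and differences are SMC minus non-SMC.

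Rb1 and Trp53, the genes targeted in this model, were detected on all 6 arrays. The Rb1 signal was -2.07, -0.38 and -2.09 in non-SMC replicates 1 to 3 and 0.63, 0.64 and 0.27 in the SMC lines. Its difference of 2.02 ± 0.45 (SE, 3 pairs) did not pass the test across all genes (limma adjusted p = 0.113); it passed with the block removed and non-SMC replicate 2 left out (2.59, adjusted p = 0.00887). Trp53 lay between -0.36 and 0.14 on all arrays, with a difference of -0.09 ± 0.30 (adjusted p = 0.867). The position of these probes relative to the deleted exons was not examined, so they do not check the deletion. The X-inactivation transcript Xist lay between 4.50 and 5.42 in pairs 1 and 3 and at -7.74 and -6.79 in pair 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were well above background in both lines of pair 2 and in no other line. Ddx3y, also Y-linked, was detected only in non-SMC replicate 2, at -0.03, against -8.30 in its SMC partner. Pou2f3 was well above background on no array.

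Lines of the same group resembled each other more than lines of the same pair. Across features, the correlation was 0.918 to 0.945 among SMC lines and 0.871 to 0.931 among non-SMC lines, against 0.731 to 0.861 within pairs. Features are not independent replicates, so these correlations carry no p-value.

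The comparison of SMC with non-SMC lines asks which genes distinguish the lines of a pair. Of 33 mesenchymal and EMT genes 18 were lower in the SMC lines, and of 22 fibroblast and collagen genes 12, although neither list passed with an estimated correlation (adjusted p = 0.0904 for both). Spp1, which encodes the secreted matrix protein osteopontin, was at least 10300-fold lower in SMC than in non-SMC lines (adjusted p = 0.00704), and its probe was not well above background on any SMC array. Over the other settings, its difference ranged from -14.53 to -10.33. Vim, the intermediate filament of mesenchymal cells, fell from 6.65 ± 0.90 to -6.19 ± 0.47 (SD, n = 3), a difference of -12.84 ± 0.55 (SE, limma adjusted p = 0.00744), and was detected on 1 of 3 SMC arrays. S100a6, a calcium-binding protein measured on all 6 arrays, differed by -12.52 ± 0.60 (adjusted p = 0.00821). The neural adhesion gene Ncam2 was higher in SMC, at 4.89 ± 0.54 (adjusted p = 0.0341). It was detected on 1 of 3 non-SMC arrays, and its difference was 3.38 with dim signals at the floor.

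In the paired limma fit, 31 features were higher and 602 lower in SMC at an adjusted p under 0.05, among them 20 and 460 features with a gene symbol. Every called feature differed by more than 2-fold and had the same sign in all 3 pairs, and the smallest absolute difference was 2.14. On the SMC arrays, 274 of the 602 lower features were never well above background. The non-SMC arrays likewise never measured 17 of the 31 higher ones. At an unadjusted p under 0.05, 2964 features were higher and 2338 lower. Without the pair in the fit, 274 features were higher and 975 lower, and with the median in place of the 75th percentile, 239 and 974. The median difference over all features was 0.18, 0.10 with median scaling and 0.08 with normexp background correction.

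These counts depended on which lines entered. Without pair 1, 0 features were higher and 207 lower (1490 and 2013 at an unadjusted p under 0.05). Without pair 2 the counts were 523 and 496. Without pair 3 limma called 0 in both directions, with 924 higher and 1743 lower at an unadjusted p under 0.05. With the replicate block removed and non-SMC replicate 2 left out, an alternative chosen after its values were seen, 1559 features were higher and 1147 lower. The same fit without non-SMC replicate 3 gave 17 and 432.

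The 4 arrays of 1 slide held both groups: SMC replicates 1 and 2 and non-SMC replicates 2 and 3. Non-SMC replicate 1 and SMC replicate 3 each lay alone on a slide. Only pair 2 had both lines on the same slide, so in pairs 1 and 3 the group difference is also a difference between slides. On the shared slide of 4 arrays alone, with 2 lines per group and no pairing, 20 features were higher and 612 lower. With the slide as a block beside the pair, 9 were higher and 466 lower. This block set the shared slide against the other slides pooled as 1 level, so it did not adjust for each slide. All 6 arrays were scanned on 1 day.

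Differences were correlated between pairs, across features that are not independent replicates. The correlation of the SMC minus non-SMC differences was 0.619 between pairs 1 and 2, 0.667 between pairs 1 and 3, and 0.706 between pairs 2 and 3, and Spearman's rho was 0.533, 0.591 and 0.611. The same sign in all 3 pairs was found for 55.5% of features, against 25% by chance. Pair 2 had fewer large increases: 312 features were higher in SMC by more than 2 on the log2 scale, against 2676 in pair 1 and 2367 in pair 3, while 1758, 1981 and 2140 were lower by as much in pairs 2, 1 and 3. Pair 2 was also the only pair with both lines on the same slide.

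**Figure D1:**
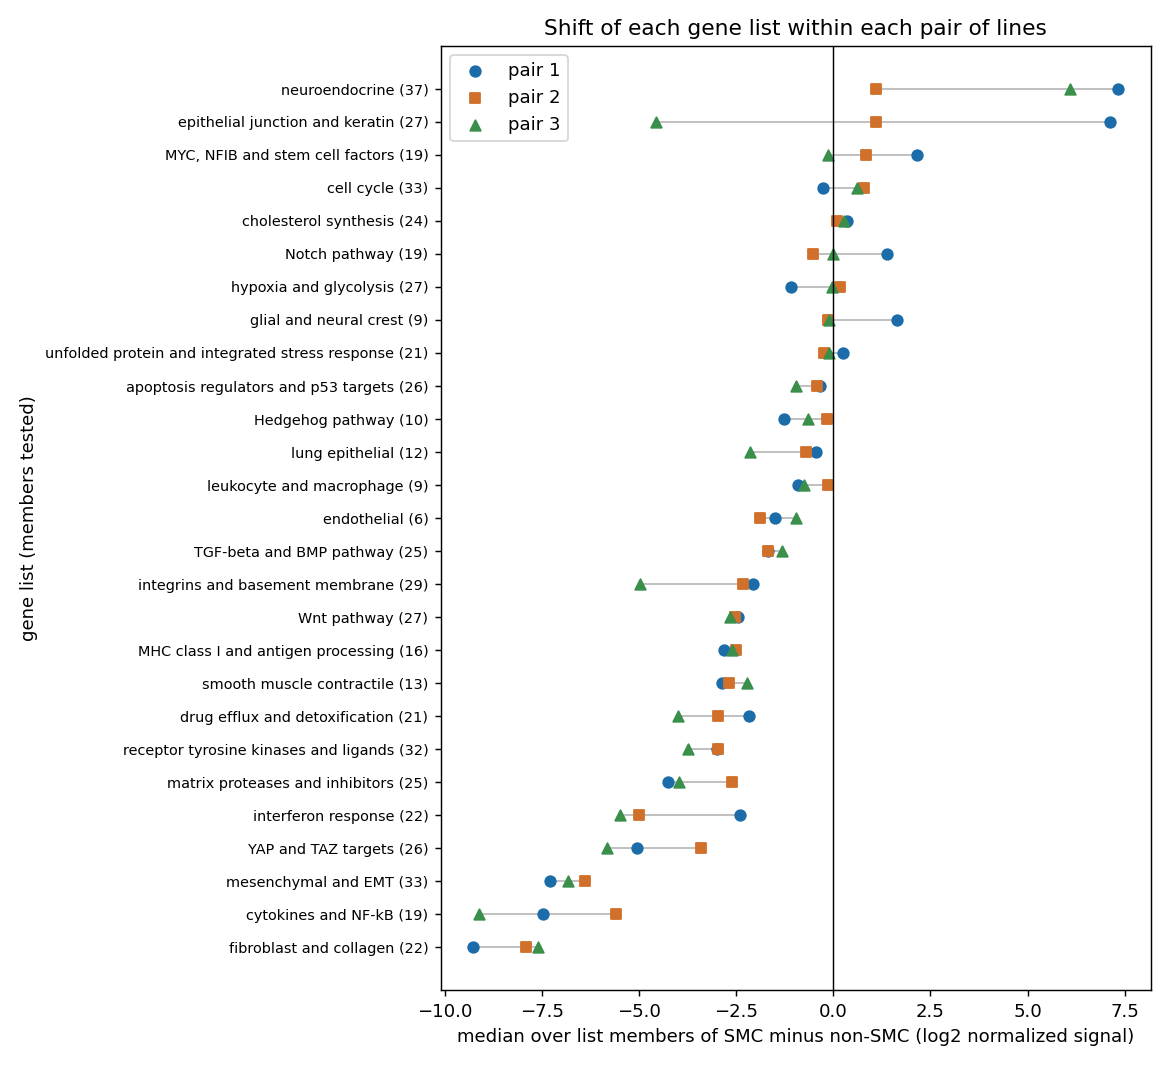
Median SMC minus non-SMC difference (log2, x axis) over the tested members of each of the 27 gene lists (y axis, number of members in parentheses), with 1 point per pair of lines. The neuroendocrine list lies at 7.33, 1.10 and 6.09 in pairs 1 to 3, the epithelial list at 7.12, 1.11 and -4.57, and the fibroblast and collagen list under -7 in every pair.

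Of the 27 gene lists fixed before the data were examined, 2 were higher and 18 lower in SMC by camera with a preset inter-gene correlation of 0.01. No list passed with an estimated correlation, where the smallest adjusted p was 0.0904; with an estimated correlation and without the pair in the fit, a setting chosen after the data were seen, 12 lists passed, the smallest adjusted p being 0.0282. By comparison, 16 passed by fry, which does not compare a list with other genes. In some lists the estimated correlation was under the preset 0.01, as for YAP and TAZ targets (-0.0042) and MHC class I (-0.038). Their calls were lost as well, so a higher correlation does not account for all the losses. With an estimated correlation, camera also takes its degrees of freedom from the residuals of the fit, 2 here, rather than from the number of genes. A call lost in this form therefore does not by itself show that the genes of a list are correlated. The figures given per list are members past the test over all features, then members adjusted over the list alone.

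Mesenchymal and matrix genes were lower in the SMC lines. Of the 33 measured mesenchymal and EMT genes, 18 were lower, 15 did not pass and none was higher, and 25 were lower adjusted over the list alone (camera adjusted p = 3.25e-20, 0.0904 with an estimated correlation). Besides Vim and S100a6, they included Sparc, a collagen-binding glycoprotein, at -11.74 ± 0.51 (detected on 2 of 3 SMC arrays), and the receptor kinase Axl, at least 239-fold lower. Among 22 fibroblast and collagen genes, 12 were lower and 10 did not pass, with 16 lower adjusted over the list alone (adjusted p = 1.52e-14, 0.0904 with an estimated correlation). By their brightest probes, the collagen genes Col3a1, Col1a1 and Col6a1 were at least 2320-fold, 1530-fold and 1280-fold lower. Other probes gave smaller differences, -5.26 for Col3a1 and -10.1 to -6.59 for Col1a1. Col1a2, measured on all arrays, differed by -11.76 ± 0.61. The list's median was -8.46, and -8.09 with dim probes at their bound; for the mesenchymal list it was -6.30 and -6.20. On the shared slide alone, the medians of the mesenchymal and fibroblast lists were -6.76 and -8.29 (adjusted p = 0.16 for both with an estimated correlation). Of 25 matrix proteases and inhibitors, 6 were lower and 17 adjusted over the list alone (adjusted p = 1.05e-11, 0.0904 with an estimated correlation). Mmp3, a matrix metalloproteinase, was at least 447-fold lower, Mmp19 at least 8.89-fold lower, and Timp1, an inhibitor of such enzymes, and the urokinase receptor gene Plaur differed by -8.55 ± 0.39 and -7.98 ± 0.31. Integrin and basement membrane genes were lower for 5 of 29 members, and 20 adjusted over the list alone (adjusted p = 1.39e-13, 0.0904 with an estimated correlation), with Itga5 at least 194-fold lower, Itga11 at -8.16 ± 0.50 (detected on 2 of 3 SMC arrays), and the laminins Lamb1 and Lama4 at -6.25 ± 0.59 and -6.00 ± 0.50. Smooth muscle contractile genes were lower for 3 of 13, and 11 adjusted over the list alone (adjusted p = 3.65e-07, 0.0904 with an estimated correlation): Mustn1 by at least 15.9-fold, Cald1 by -3.24 ± 0.37 and Tpm1 by -2.96 ± 0.33. Another Tpm1 probe differed by 0.81, in the opposite direction.

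Targets and partners of the transcriptional coactivators YAP and TAZ were lower for 10 of 26 measured genes, and for 16 adjusted over the list alone (adjusted p = 1.79e-14, 0.0904 with an estimated correlation). By their brightest probes, Ccn2, Ankrd1 and Myof were at least 5800-fold, 1330-fold and 2100-fold lower. Other Myof probes differed by -11.7 to -8.67. Wwtr1, which encodes TAZ, differed by -11.08 ± 0.40 (adjusted p = 0.00704) and was detected on 1 of 3 SMC arrays. Yap1 itself had a difference of -4.72 ± 1.23 that did not pass (adjusted p = 0.129); its SMC signals were -6.06, -1.28 and -2.80, the first not well above background. TGF-beta and BMP pathway genes were lower for 8 of 25, and 14 were lower and 1 higher adjusted over the list alone (adjusted p = 4.32e-08, 0.0904 with an estimated correlation). The activin subunit Inhba was at least 1580-fold lower, and the receptor gene Tgfbr2 and Ltbp2 differed by -10.50 ± 0.76 and -9.04 ± 0.80, each detected on 1 of 3 SMC arrays. Of 32 receptor tyrosine kinases and ligands, 7 were lower, and 18 were lower and 1 higher adjusted over the list alone (adjusted p = 1.64e-11, 0.0904 with an estimated correlation). Fgf7 and Ereg, both growth factors, were at least 63.3-fold and 11-fold lower, and Ephb4, detected on 2 of 3 SMC arrays, and Nrg1 differed by -6.07 ± 0.58 and -4.97 ± 0.40. Wnt pathway genes were lower for 4 of 27, and 12 were lower and 3 higher adjusted over the list alone (adjusted p = 4.04e-05, 0.101 with an estimated correlation). Their examples act in different ways: the secreted Wnt antagonists Sfrp2 and Sfrp1 differed by -10.74 ± 0.75 and -5.50 ± 0.38, the transcription factor Tcf7l2 was at least 146-fold lower by its brightest probe, and the receptor Fzd8 differed by -3.42 ± 0.45. Other Tcf7l2 probes differed by -7.43 to -4.7. On the SMC arrays, Sfrp2 and Fzd8 were each detected on 1 of 3 and Sfrp1 on 2 of 3. In the Hedgehog list, 1 of 10 genes was lower, also adjusted over the list alone: Gas1, at -6.76 ± 0.43, or -5.33 with dim signals at the floor, detected on 1 of 3 SMC arrays (list adjusted p = 0.04, 0.288 with an estimated correlation, 0.0708 without the pair and 0.103 without pair 1).

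Part of the genes of immune signalling and antigen presentation passed as lower in SMC. For cytokines and NF-kB, 8 of 19 were lower and 18 adjusted over the list alone (adjusted p = 7.76e-16, 0.181 with an estimated correlation), with a median of -6.65, or -5.52 with dim probes at their bound. The chemokine gene Cxcl12, detected on 1 of 3 SMC arrays, differed by -12.61 ± 1.09, or -11.20 with dim signals at the floor, and Ccl2, Il33 and Ptgs2 were at least 1690-fold, 567-fold and 543-fold lower. Interferon response genes were lower for 3 of 22, and for 16 adjusted over the list alone (adjusted p = 1.39e-10, 0.219 with an estimated correlation): Gbp2 at -8.43 ± 0.59 (detected on 1 of 3 SMC arrays), Xaf1 at -5.58 ± 0.65, and Ddx58, which encodes the RNA sensor RIG-I, at -5.21 ± 0.28. In the MHC class I and antigen processing list, 3 of 16 were lower and 15 adjusted over the list alone (adjusted p = 1.04e-09, 0.0904 with an estimated correlation). B2m, the invariant light chain of MHC class I, fell from 6.04 ± 0.58 to 0.67 ± 1.03 (SD, n = 3), a difference of -5.37 ± 0.70 (limma adjusted p = 0.0466), H2-K1 differed by -2.82 ± 0.36 and Tapbp by -2.77 ± 0.35. The leukocyte and macrophage list did not pass (adjusted p = 0.178). Of its 9 tested genes 1 was lower, Cd14 at -7.71 ± 0.70 (detected on 2 of 3 SMC arrays), and 1 was lower and 1 higher adjusted over the list alone. On the shared slide alone this list was lower (median -0.74, adjusted p = 0.00811, 0.348 with an estimated correlation), and also without a filter (adjusted p = 0.0302, 0.415 with an estimated correlation). Beside these groups stands non-SMC replicate 3, in which 17 of the 21 leukocyte list genes on the array were detected, against 9 and 12 in non-SMC replicates 1 and 2; Tyrobp, a myeloid adaptor, lay at -0.26 there and at -6.89 and -7.13 in the other non-SMC lines.

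The neuroendocrine list was higher in SMC as a group, although none of its 37 genes passed singly, also not adjusted over the list alone. Its median difference was 5.02, 36 of 37 genes were positive (camera adjusted p = 3.88e-09), and the call was lost with an estimated correlation (adjusted p = 0.443) and by fry (adjusted p = 0.154). On the shared slide alone the median was 3.73 (adjusted p = 2.38e-05, 0.495 with an estimated correlation). The largest differences, in the granin gene Chgb and the synaptic vesicle gene Syt1, were 6.16 ± 1.70 and 6.02 ± 1.93 (adjusted p = 0.137 and 0.161). Chgb was 4.29, 3.64 and 5.09 in SMC replicates 1 to 3 and -5.41, 2.02 and -2.07 in non-SMC replicates 1 to 3. Non-SMC replicate 2 lay closer to its SMC partner than the other non-SMC lines did, and the list's median difference was 1.10 in pair 2 against 7.33 and 6.09 in pairs 1 and 3. Both lines of pair 2 lay on the same slide, as did non-SMC replicate 3, whose Chgb signal was -2.07. Without pair 2, a planned setting, 21 of the 37 genes were higher (list median 6.81, camera adjusted p = 1.28e-18, 0.341 with an estimated correlation). With the block removed and only non-SMC replicate 2 left out, 29 of the 37 genes were higher, Chgb by 8.09 (limma adjusted p = 0.0134). The list's camera adjusted p with an estimated correlation was still 0.0839. Neurod1 was detected only in pair 2, at -3.63 in the non-SMC and -1.67 in the SMC line.

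**Figure D2:**
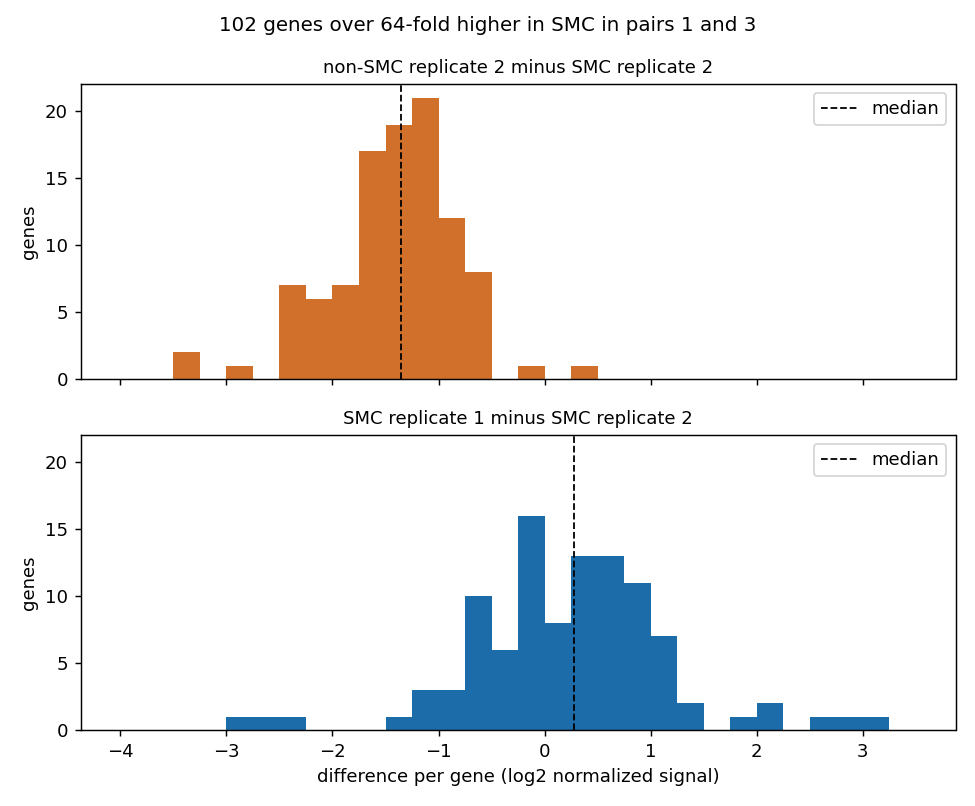
Number of features (y axis) by their log2 difference (x axis) between non-SMC replicate 2 and SMC replicate 2 (top) and between SMC replicates 1 and 2 (bottom), over 102 features at least 64-fold higher in SMC in pairs 1 and 3. The dashed lines are medians, and the upper one lies at -1.36, where the interquartile range is 0.626 against 0.999 in the lower panel.

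**Figure D3:**
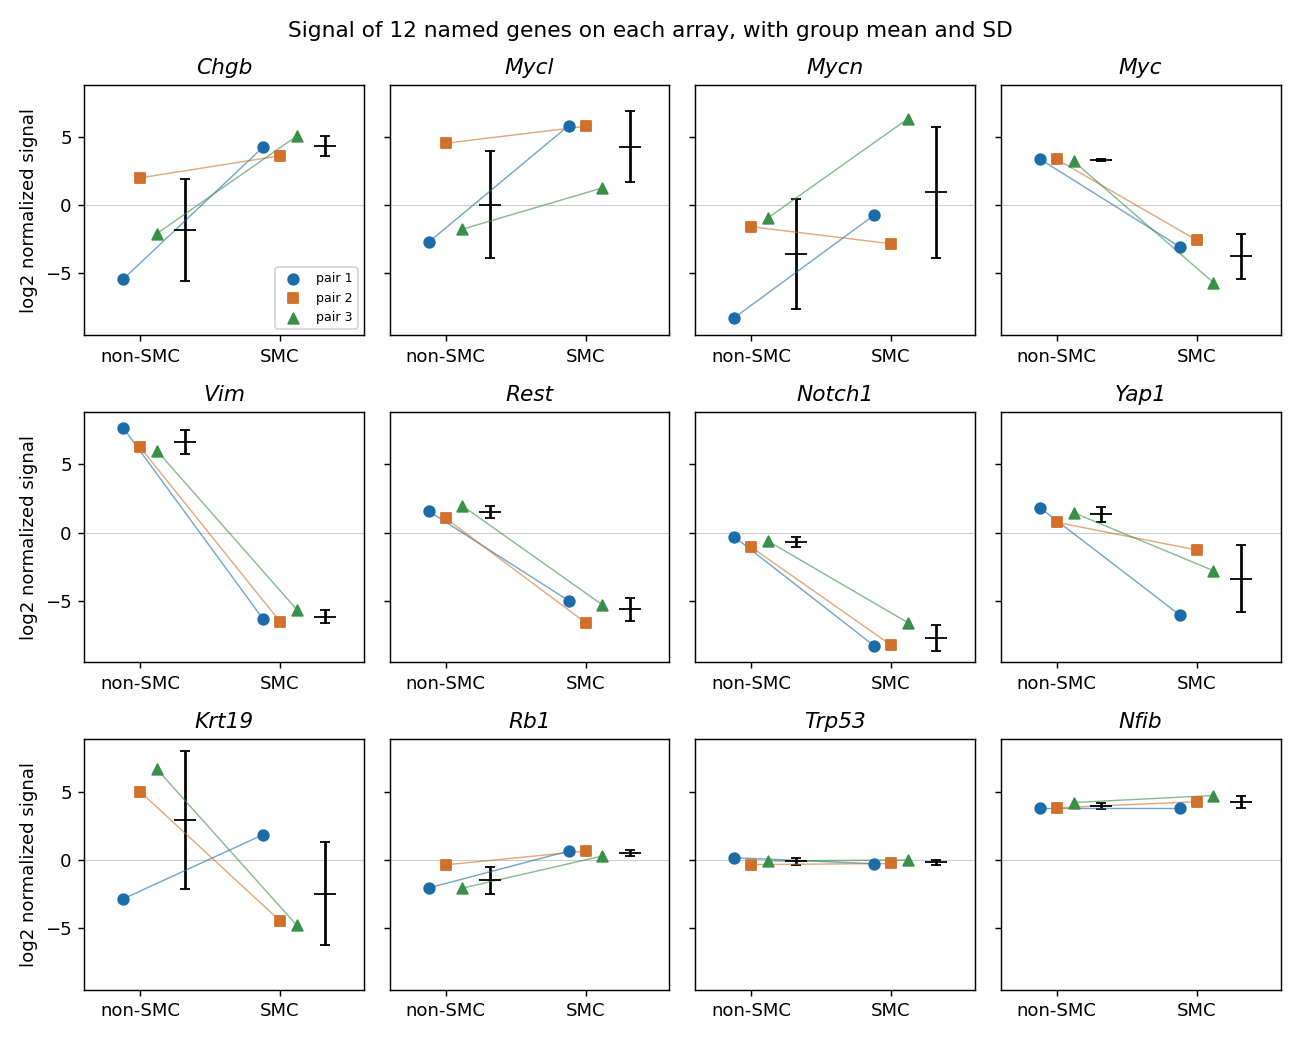
Log2 normalized signal (y axis) of 12 genes in the non-SMC and SMC line of each pair (x axis), with points joined within pairs and the group mean ± SD (n = 3) as a black bar. Vim, Rest, Notch1 and Myc are separated by group in every pair, while Chgb in non-SMC replicate 2, at 2.02, lies nearer to the SMC lines than in the other non-SMC lines.

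The 12 named genes with the largest increases in SMC had low signals in the non-SMC lines, with group means from -8.36 for Dnah2 to -4.17 for Lin7a. Gpr37, a receptor found in the nervous system, and Robo2, a receptor of axon guidance, were at least 11.8-fold and 5.13-fold higher, with non-SMC probes not well above background. Dnah2, Gng4 and Rnf180 were at least 3.93-fold, 3.64-fold and 2.81-fold higher, although another Dnah2 probe was detected on a non-SMC array. The remaining 7 were detected on 1 or 2 of 3 non-SMC arrays: besides Ncam2, these were Lin7a, a synaptic scaffold gene, at 4.54 ± 0.51, Slc10a4 at 4.12 ± 0.47, Rab17 at 4.03 ± 0.40, Apoa5 at 3.99 ± 0.30, Pip5kl1 at 3.97 ± 0.35 and Ocm at 3.93 ± 0.45 (adjusted p from 0.0168 to 0.0366). With dim signals at the floor, the difference of Ocm was 2.77. With normexp background correction, 1 of these 12 genes passed, Lin7a, and without pair 1 or without pair 3 none did. The 12 largest decreases all passed with normexp, 9 of them passed without pair 1 and none without pair 3. They include, besides those above, the annexins Anxa3 at -13.19 ± 0.67 and Anxa8, at least 3030-fold lower, and S100a11 at -12.26 ± 0.73; Anxa3 and S100a11 were each detected on 1 of 3 SMC arrays, and differed by -12.02 and -11.61 with dim signals at the floor.

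Regulators of cell identity moved unevenly. Rest, a repressor of neuronal genes, was lower at -7.17 ± 0.36 (adjusted p = 0.00821) and was detected on 2 of 3 SMC arrays. Notch1 was at least 49.4-fold lower and Notch2 differed by -3.41 ± 0.41, whereas Hes1, a Notch target, had a difference of -3.86 ± 1.37 that did not pass (adjusted p = 0.183). The Notch list as a whole did not pass (3 of 19 lower, and 4 lower and 1 higher adjusted over the list alone; adjusted p = 0.38). In the list of MYC, NFIB and stem cell factors, 3 of 19 were lower, and 3 were lower and 1 higher adjusted over the list alone (adjusted p = 0.882; its median was 1.19 and its mean -0.10). Myc fell by 7.10 on the log2 scale, with an SE of 0.71 (adjusted p = 0.0282), from 3.34 ± 0.08 to -3.75 ± 1.68 (SD, n = 3). The surface antigen gene Ly6a was at least 622-fold lower and Sox9 differed by -8.04 ± 1.00, or -6.56 with dim signals at the floor, detected on 1 of 3 SMC arrays. Mycl and Mycn did not pass (adjusted p = 0.189 and 0.247): Mycl was 5.86, 5.81 and 1.28 in SMC replicates 1 to 3, and Mycn was -0.71, -2.82 and 6.36. Mycn was detected on 2 of 3 non-SMC arrays. Over the other settings its difference ranged from -0.52 to 7.41 and its limma adjusted p from 0.0306 to 0.716. Nfib was 3.93 ± 0.23 in non-SMC and 4.26 ± 0.46 in SMC lines (SD, n = 3; limma adjusted p = 0.528).

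Epithelial genes did not separate the groups. None of 27 measured junction and keratin genes passed, also not adjusted over the list alone (list adjusted p = 0.59), and the pairs went opposite ways: the median difference was 7.12 in pair 1, 1.11 in pair 2 and -4.57 in pair 3. Without pair 1 the list was lower (median -1.76, adjusted p = 0.00616, 0.672 with an estimated correlation), without pair 3 it was higher (median 3.96, adjusted p = 2.54e-07, 0.573 with an estimated correlation), and with the slide block it was higher (adjusted p = 0.00395, 0.331 with an estimated correlation). Krt19 differed by 4.71, -9.49 and -11.48 in pairs 1 to 3 (adjusted p = 0.387), and Tjp3, a tight junction gene detected on 2 of 3 non-SMC arrays, by 7.91, 1.44 and 0.81 (adjusted p = 0.264). Cdh1 was detected in SMC replicate 1, in both lines of pair 2 and in non-SMC replicate 3, at -1.25 to -0.44, and not well above background in the other lines, so it was not tested.

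Cell cycle genes were slightly higher as a list (median 0.41, 27 of 33 positive, camera adjusted p = 0.04), but none passed singly or adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.633), with median scaling (adjusted p = 0.13) and without pair 2 or pair 3. The list's median was -0.26, 0.79 and 0.61 in pairs 1 to 3, so pair 1 went the other way. Ccne2 and Mki67 had differences of 2.03 ± 0.36 and 1.03 ± 0.29 (adjusted p = 0.085 and 0.139). Drug efflux and detoxification genes were lower for 5 of 21, and 14 adjusted over the list alone (adjusted p = 5.79e-09, 0.0904 with an estimated correlation), with Cyp1b1 at -8.35 ± 0.75, Mgst1 at -8.11 ± 0.66, Gsta4 at -5.01 ± 0.38 (detected on 2 of 3 SMC arrays) and Abcb1b at -4.92 ± 0.41. Among apoptosis regulators and p53 targets, 3 of 26 were lower and 7 adjusted over the list alone (adjusted p = 0.00252, 0.219 with an estimated correlation). The death receptor gene Fas was at least 207-fold lower, the inflammatory caspase gene Casp4, detected on 1 of 3 SMC arrays, differed by -8.42 ± 0.35, and Cdkn2b, a cell cycle inhibitor, by -6.05 ± 0.61. Hypoxia and glycolysis genes (median -0.36, adjusted p = 0.04, 0.571 with an estimated correlation) and genes of the unfolded protein and integrated stress response (median -0.54, adjusted p = 0.0305, 0.219 with an estimated correlation) were lower as lists, with no member past the test, also not adjusted over the list alone. The hypoxia call was also lost with median scaling (adjusted p = 0.055) and without pair 1 (adjusted p = 0.345), and the stress response call without pair 2 (adjusted p = 0.119) or pair 3 (adjusted p = 0.0616). In pairs 1 to 3 the hypoxia median was -1.08, 0.18 and -0.03, and the stress response median 0.24, -0.24 and -0.12, so neither had the same sign in every pair. Hk2, detected on 2 of 3 SMC arrays, and P4ha2 had differences of -5.98 ± 1.39 and -3.26 ± 0.91, and Slc7a11 and Ppp1r15a of -2.06 ± 0.56 and -1.39 ± 0.66. The cholesterol synthesis list did not pass (median 0.26, camera adjusted p = 0.405), and none of its 24 genes did, also not adjusted over the list alone. Tm7sf2 had a difference of 1.13 ± 0.80. The list was higher by fry (adjusted p = 0.0463) and on the shared slide alone (median 0.79, camera adjusted p = 0.0112, 0.495 with an estimated correlation).

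Markers of other cell types gave these values. The endothelial list was lower (adjusted p = 0.025, 0.219 with an estimated correlation), with 1 of 6 genes lower, and 2 adjusted over the list alone; the gene was the VEGF receptor Flt1, at -8.16 ± 0.49 and detected on 1 of 3 SMC arrays, and the call was lost with normexp (adjusted p = 0.0587), without pair 2 (adjusted p = 0.0746) and without a filter, over 15 members (median -0.051, adjusted p = 0.192). The lung epithelial list did not pass (adjusted p = 0.0717), with 1 of 12 genes lower, also adjusted over the list alone: the water channel gene Aqp5, at -6.45 ± 0.70. The list was lower without pair 1 (adjusted p = 0.00761, 0.362 with an estimated correlation), on the shared slide alone (adjusted p = 0.0458, 0.278 with an estimated correlation) and without a filter (adjusted p = 0.00536, 0.391 with an estimated correlation). The glial and neural crest list did not pass (adjusted p = 0.882), with 0 of 9 genes over all features and 1 lower adjusted over the list alone; Nes and Pmp22 had differences of -4.02 ± 0.73 and -2.21 ± 0.80.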

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

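The tests of mixing, normalization, an intermediate level, SMC cells in non-SMC replicate 3, leukocytes and dim probes were chosen after all or part of the values they measure had been seen; those of exchanged labels and of other splits were set before their results.

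Non-SMC replicate 2 carried neuroendocrine signal at an intermediate level. A set of 102 features was at least 64-fold higher in SMC in pairs 1 and 3 and above the array's 75th percentile in SMC replicate 2. Over these, non-SMC replicate 2 held a median share of 39.1% of the SMC replicate 2 signal. The interquartile range of the log2 share was 0.626, against 0.999 between SMC replicates 1 and 2. This set was chosen without non-SMC replicate 2, but its condition on SMC replicate 2 can by itself lower the share. Another set held 71 features at least 64-fold lower in SMC in those pairs and above background on no SMC array. Over these, non-SMC replicate 2 kept 49.8% of the signal of the other non-SMC lines. The interquartile range was 1.38 (log2), against 1.39 between non-SMC replicates 1 and 3. This set was chosen by the signals of non-SMC replicates 1 and 3, which can by itself lower the share kept by replicate 2. Both shares sum to 0.889. Because the selection can lower this sum, it does not decide whether the culture held cells like its SMC partner. A shift of the whole array is argued against, since the 75th percentiles of non-SMC replicates 2 and 3, on the same slide, were near each other (570.2 and 547.4). Over 4 normalizations, the neuroendocrine list stayed above non-SMC replicate 3 by a median of at least 3.1. These normalizations act on whole arrays and could not remove a gap confined to such a list, so they decide nothing further. Cells that all sit at an intermediate level would allow the same spread of 0.626, and bulk RNA does not separate the 2, so this stays open.

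Epithelial genes stood out because the pairs moved in opposite directions; the difference between pairs was not tested, since each pair is 1 comparison. The epithelial list's median difference was 7.12 in pair 1 and -4.57 in pair 3, Krt19 gave 4.71 and -11.48, and Mycn, for the same reason, gave 7.55 in pair 1 and -1.25 in pair 2. SMC cells mixed into non-SMC replicate 3 are argued against, because relative to SMC replicate 1 its epithelial genes lay 5.89 (log2) above its neuroendocrine genes. Exchanged labels of non-SMC replicates 1 and 3 remain open: over 263 features higher in SMC, the correlation of the non-SMC difference with the SMC difference between pairs 3 and 1 was -0.0436, too close to 0 to decide, and both pairs are labelled female, although single genes picked after their values were seen ran as labelled (Igf2 at -7.09 and -7.04 in pair 1 against -1.83 and 0.33 in pair 3, and Zic1, Vsnl1 and Lyz1, given with the other observations). Over all features, deviations from the group means correlated at 0.13 between non-SMC replicate 1 and SMC replicate 3, but at -0.032 between non-SMC replicate 3 and SMC replicate 1. Non-SMC replicate 1 and SMC replicate 3 are also the arrays off the shared slide, and a slide effect could give the 0.13 too. As labelled, pairs 1 and 3 gave -0.013 and -0.0024, so these values do not decide either. A difference between the tumours is untested.

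Leukocyte genes stood out in non-SMC replicate 3. Over the 21 leukocyte list genes on the array it exceeded the higher of the other non-SMC lines by a median of 1.58 (log2), 13 of them by over 1, while the endothelial list gave -0.22. Leukocytes in the culture may account for this, with Lyz2 at -1.05, Tyrobp at -0.26 and Adgre1 at -2.29, although Csf1r, at -4.78, was no higher than in non-SMC replicate 1, Coro1a, at -0.88, lay under its 2.43 in non-SMC replicate 2, and Lyz1 and Lyz2, at 3.45 and 0.12 in SMC replicate 3, were higher there than in this line. A general rise of dim probes is argued against by the gap of 1.80 between both lists. Expression of such genes by the tumour line itself was not tested.

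Other splits of the 6 arrays were also fitted. Without the pair, the real grouping called 1249 features and the highest other of the 10 splits 0. With the pair, it called 633 and the highest other of the 4 splits that part every pair 0; the others exchange the lines of 1 pair. In each model 1 split, the real one, reached its own count, but so few splits cannot give a share under 0.05.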

How the results depend on the processing

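Leaving out non-SMC replicate 2 or 3 without the block, and the estimated correlation without the block, were chosen after the data were examined; all other settings were planned. Of the 78 named genes past the threshold, none changed sign in any setting, and 1002 of 1269 comparisons stayed past it; without pair 3 none of the 78 passed, and without pair 1 29 did. Of the named genes not past it, Rb1 and Ccne2 passed only without non-SMC replicate 2 and the block. The replicate block moved the counts: without it 274 features were higher and 975 lower, 7 of the 78 genes no longer passed, the Hedgehog list lost its call, and no other list call changed with the preset correlation. Against 31 higher and 602 lower features, median scaling gave 239 and 974, no filter 7 and 383, and detection on all arrays 4 and 135, the last with 16358 features tested and without most genes that are off in a group. Higher features numbered 54 with normexp, 9 with the slide block and 20 on the shared slide alone. Leaving out each pair gave 0 to 523 higher and 0 to 496 lower features. Without non-SMC replicate 2 and the block, 1559 were higher and 1147 lower, and without non-SMC replicate 3, 17 were higher. With an estimated correlation 0 of 27 lists passed, against 20. With detection on all arrays the Wnt, Hedgehog, apoptosis and endothelial lists lost their calls. The agreement of pairs, as a mean correlation, was 0.664, but 0.544 without a filter and 0.5585 with detection on all arrays. The share of features with 1 sign in all pairs was 55.5%, but 47.5% with median scaling, 43.0% without a filter and 52.0% with detection on all arrays. Higher calls made up 4.9% of all calls, 19.7% with median scaling, 21.9% without the block and 51.3% without pair 2. Except for fewer features or lines, the cause of these shifts was not tested.

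Tested directions turned only where no call stood in the planned fit; among called lists, the median turned for hypoxia without pair 1 (0.045) and for apoptosis with detection on all arrays (0.037), and the endothelial mean with detection on all arrays (0.84), where these calls were lost. The epithelial list ranged from -1.76 to 3.96 when pairs were left out. The glial list, whose median (0.25) and camera test already differed in sign, turned upward without pair 2 or pair 3 (medians from -0.035 to 0.46 over the left-out pairs), without non-SMC replicate 2 (0.25) or 3 (0.42) and the block, and by fry (0.25). The list of MYC, NFIB and stem cell factors turned downward in the test without the block (median 1.19), on the shared slide (0.53), without pair 1 (0.30) and by fry (1.19), and its median ranged from 0.30 to 1.49 when pairs were left out. Trp53 ranged from -0.18 to 0.081 when pairs were left out, and Mycn was -0.52 on the shared slide. As for signal over background, 11 of the 12 named genes with the largest increases no longer passed with normexp, although normexp called more higher features in all; the cause was not tested.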

Other observations

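The genes in this part were chosen after their values were seen. Single X-linked genes differed between pairs: Rhox2a lay at 2.38 and 3.93 and Xlr4b at 1.64 and 2.58 in the non-SMC and SMC line of the same pair, and both were under -4 in all other lines. Igf2, an imprinted growth factor gene, was 4.38 and 4.14 in pair 2, -1.83 and 0.33 in pair 3, and about -7 in both lines of pair 1. Such pair-specific signals lie outside the comparison of the groups, since both lines of a pair share them.

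SMC replicate 3 differed from the other SMC lines. Zic1, a neural transcription factor, was 2.90 there and under -7 in the other SMC lines, Vsnl1 was 2.56 against -8.70 and -8.48, and Lyz1 3.45 against -5.94 and -3.74. Its non-SMC partner had weaker signals of the same genes, at -3.49, -3.78 and 1.94. In the same line Mycn was high and Mycl low, as given above. Sftpc, a surfactant gene, was highest in SMC replicate 1, at 3.76, and between -4.16 and -0.34 in the other lines. Non-SMC replicate 3 had the basal keratin genes Krt5 and Krt14 at 1.85 and 0.90, each under -3 in every other line. Ddx3y was not well above background in SMC replicate 2 although Eif2s3y was the same in both lines of the pair (1.09 and 1.02).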
